A study of Mus musculus with 6 samples.

How the data were processed

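RNA sequencing was performed on osteoblasts, the cells that build bone, taken from the calvaria (the flat bones of the skull) of mouse pups aged 5 days on the C57Bl/6J background. Per the labels' protocols, the calvaria were digested with collagenase, and cells carrying a GFP transgene under the control of Osteocalcin-Cre, a recombinase expressed in osteoblasts, were collected by flow cytometry into Trizol. The labels assign 3 libraries to a conditional knockout of Cdc73, also called Hrpt2, and 3 libraries to wildtype mice. They do not state whether each library came from a separate animal, litter or pool, so the p-values measure the spread between these samples, which may be partly technical. The way RNA was selected for the libraries, the strandedness of the reads and the exons removed by the deletion are not given in the sources used here.

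The deposited values were raw counts of reads per gene, whole numbers with no normalization, in 1 table of 27179 gene IDs by 6 libraries. Per the submitters' processing notes, CASAVA version 1.7, Subread and featureCounts were used with the mouse genome build mm10. Every column of the table was assigned to a sample by its name, and 0 columns were left over. Gene names were taken from the NCBI RefSeq table of the same mouse assembly, which named 25275 IDs, and from GENCODE release M21, which named a further 18. The remaining 1886 IDs have no name in these reference tables and were kept in all totals and tests. Overall 93.1% of the IDs had a name. Because strand use in counting is not given, reads of overlapping or antisense genes cannot be told apart, and near-identical copies such as Bglap and its neighbours, Hba-a1 and Hba-a2, and the histone genes can share reads.

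The libraries labelled knockout 1, 2 and 3 held 16380767, 14837272 and 14958335 counts, and those labelled wildtype 1, 2 and 3 held 20993962, 13591925 and 15570605. No pair of libraries matched within sampling noise. The chi-square statistic per degree of freedom between pairs ran from 19.7 to 150.3, so all 6 were treated as distinct.

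The comparison of knockout with wildtype used edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its default settings, libraries were scaled with TMM factors (0.813 to 1.09), and each of the 13505 remaining genes was tested with the two-sided quasi-likelihood test on all 6 libraries without covariates. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are given as CPM, counts scaled to a common library total, after TMM scaling, as mean ± SD over 3 libraries, and fold changes as log2 of knockout over wildtype ± standard error. The estimated biological coefficient of variation was 24.2% over both groups, 15.4% among the libraries labelled knockout and 26.9% among those labelled wildtype.

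Gene lists were written from textbook knowledge before the data were examined, together with the tests and most alternatives. They comprised 32 lists with 503 entries, some symbols standing in several lists, and 3 symbols (Hbb-bt, Hbb-b2 and Ahsp) matched no ID. The sex-linked list only described the libraries. The other 31 were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, and adjusted over the 31 lists. Medians of lists are medians of the edgeR log2 fold changes of the tested members. Beside each list, member genes were also adjusted over the list alone.

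Genes were named by a rule fixed before the data were examined. It took Cdc73, the 10 largest changes in each direction among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups or, with none past it, the 5 of smallest p in each direction, up to 4 members of smallest p in each list, and 13 genes whatever their result (Runx2, Sp7, Col1a1, Alpl, Ibsp, Bglap, Dmp1, Sost, Tnfsf11, Tnfrsf11b, Cdkn1a, Mki67 and Axin2). Genes known only by a clone or model number were passed over in the part that ranks all genes. Col2a1, Rmrp, Malat1, Neat1, Lars2, mt-Rnr1 and mt-Rnr2 were chosen after their values were seen. Some genes that the rule takes, and member counts that rest on them, are not reported here.

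The alternatives comprised DESeq2's size factors, upper-quartile factors and library size alone in place of TMM, no filter and a stricter filter (a CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0, limma voom with and without sample quality weights, the replicate number as a block, and leaving out each library in turn. For the lists, camera with an estimated correlation and the rotation test fry were also run. Chosen after seeing the data were robust edgeR estimates, the removal of unnamed IDs and Lars2, the removal of trends on transcript length and GC content, voom without wildtype 1, camera with an estimated correlation without wildtype 1, and wildtype 1 as the only control, a fit in which the lone control is assumed to vary like the knockout libraries. The p-values of that last fit measure no spread between wildtype libraries, and its list tests used the preset correlation only.

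The gene test was tested on simulated counts for the same 13505 genes with the estimated dispersion. The 200 changed genes were drawn from those with a mean of at least 5 CPM, so the rates do not cover genes of lower level. It recovered 6% of genes changed 1.5-fold, 48% changed 2-fold, 96% changed 4-fold and 100% changed 8-fold, and called 9 of 13305 unchanged genes. In the list test, the 1 raised list was called, as was 1 of 30 unchanged lists. Genes were drawn independently, with the same dispersion in both groups and in a single run. In the data, the correlation estimated within lists had a median of 0.321. The simulation therefore cannot show how often camera at the preset correlation calls unchanged lists here.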

Results

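Transcript levels were measured by RNA sequencing in GFP-sorted calvarial osteoblasts of neonatal mice, with 3 libraries labelled knockout for Cdc73 and 3 labelled wildtype. Cdc73 encodes parafibromin, a subunit of the Paf1 complex that accompanies RNA polymerase II during transcription. The series title links loss of this gene in osteoblasts to bone mass and bone turnover, and the comparison asks which transcripts differ between the sorted cells of both genotypes. Library totals ranged from 13591925 counts in wildtype 2 to 20993962 in wildtype 1. Col1a1, which encodes the main collagen chain of bone, took 14.85%, 13.92% and 17.46% of the counts in knockout 1, 2 and 3 and 18.38%, 19.62% and 19.95% in wildtype 1, 2 and 3. The most abundant feature not named in the reference tables, gene ID 100861531, took 16.66%, 20.58% and 20.68% of the knockout counts and 11.23%, 9.67% and 10.44% of the wildtype counts.

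The libraries did not separate fully by label. Wildtype 1 correlated with the knockout libraries at Pearson's r of 0.973 to 0.983 across genes (log2 CPM, genes not being independent replicates). With wildtype 2 and 3 it correlated at 0.94 and 0.945. Wildtype 2 and 3 in turn each correlated better with wildtype 1 than with any other library. On counts, chi-square per degree of freedom, in which the most abundant features weigh most, placed wildtype 1 nearest to wildtype 2 (32.3). It was 58.1 with wildtype 3, and 56.8, 78.3 and 75.3 with knockout 1, 2 and 3. These values are therefore not separate from the shares of the most abundant unnamed feature given above. After thinning to equal totals, 17794, 17615 and 16933 gene IDs had a count in knockout 1, 2 and 3 and 17373 in wildtype 1, against 14608 in wildtype 2 and 15650 in wildtype 3.

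**Figure D1:**
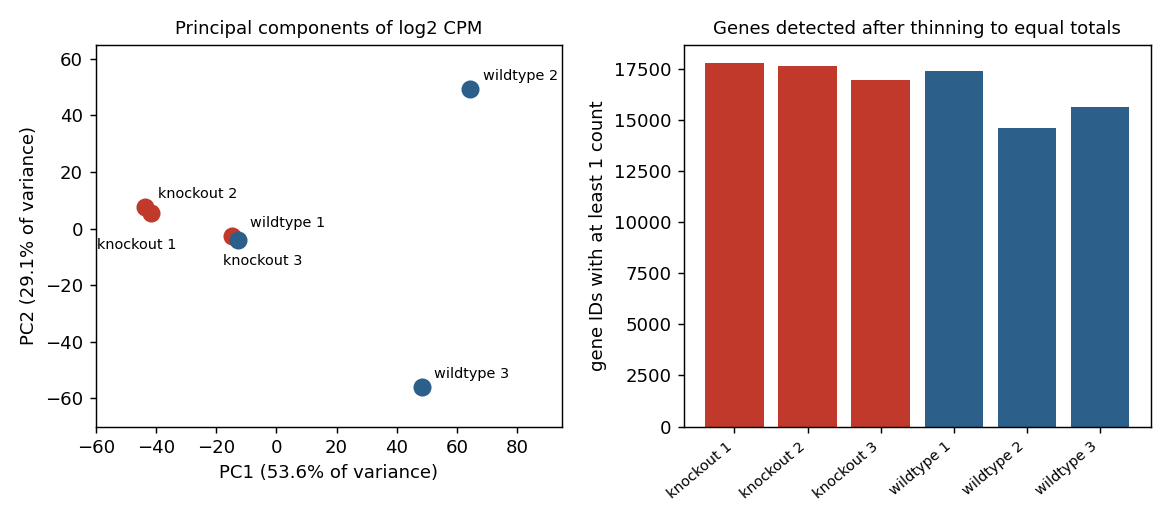
Left, the first 2 principal components of log2 CPM, with 53.6% and 29.1% of the variance, 1 point per library (red knockout, blue wildtype). Right, the number of gene IDs with at least 1 count per library after thinning to equal totals, lowest in wildtype 2 (14608) and wildtype 3 (15650).

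Cdc73 itself (gene ID 214498, chromosome 1, 143603276 to 143702893 in mm10) was detected in all 6 libraries. It measured 13.98, 14.73 and 14.40 CPM in the libraries labelled knockout 1, 2 and 3 (233, 212 and 175 counts) and 20.50, 12.80 and 21.73 CPM in those labelled wildtype 1, 2 and 3 (469, 184 and 364 counts). The means were 14.4 ± 0.38 and 18.3 ± 4.84 CPM (SD, n = 3 each), a log2 fold change of -0.36 ± 0.22. The difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.428), and wildtype 2 lay below every library labelled knockout. The count covers the whole gene, and reads from exons outside the deleted part would not report the deletion. The level of Cdc73 therefore did not check every label, and all directions below refer to the libraries as labelled.

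**Figure D2:**
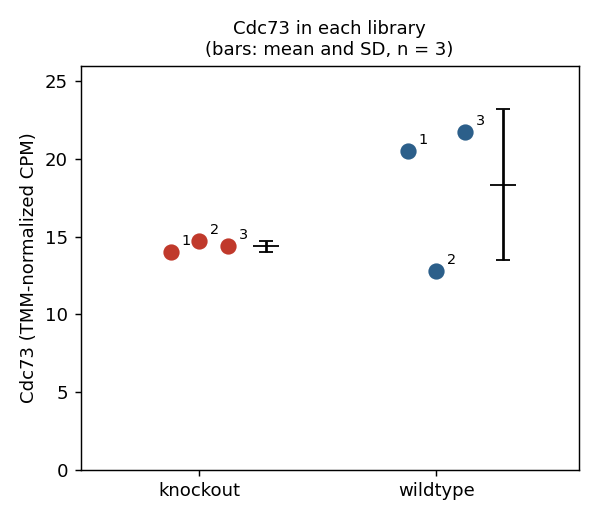
Cdc73 in TMM-normalized CPM, 1 point per library, with the mean and SD of 3 libraries beside each group. The knockout libraries lie between 13.98 and 14.73 CPM, and wildtype 2 lies below them at 12.80 CPM.

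Among genes with a mean of at least 5 CPM, the 5 of smallest p that were higher in every library labelled knockout were Arl4d, Rpph1, Snora73a, Rn7sk and Sema7a. Arl4d (gene ID 80981), a small GTPase related to ADP-ribosylation factors, measured 55.2 ± 8.56 CPM against 20.9 ± 3.45 in wildtype, a log2 fold change of 1.40 ± 0.19. Sema7a (gene ID 20361), a membrane-anchored semaphorin, measured 33.5 ± 6.47 against 15.8 ± 0.965 CPM (1.09 ± 0.18). The other members of this group were structural RNAs, namely the ribonuclease P RNA Rpph1 (1.23 ± 0.17), the small nucleolar RNA Snora73a (1.84 ± 0.29) and the 7SK RNA Rn7sk (1.27 ± 0.20). The 5 genes of smallest p that were lower in every library labelled knockout were cell division genes. They were Cdc20, an activator of the anaphase-promoting complex (-0.89 ± 0.19), the mitotic kinase Plk1 (-0.88 ± 0.20), the mitotic regulator Pimreg (-1.26 ± 0.28), the centromeric kinesin Kif2c (-1.16 ± 0.26) and the spindle protein Tacc3 (-0.68 ± 0.15). None of these 10 genes passed the threshold, with adjusted p of 0.244 for Arl4d and Rpph1 and 0.273 for the other 8 in edgeR's quasi-likelihood test.

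Over all 13505 genes tested, edgeR called 0 genes. At an unadjusted p under 0.05 there were 1974 genes, 1116 higher and 858 lower, where chance alone would give 675. In 1428 genes every knockout library lay above every wildtype library and in 1325 every one lay below, together 20.4% of genes against 10% by chance. Both chance values are averages, and genes that move together make such counts vary widely. Grouping wildtype 1 with knockout 1 and 2 gave 1991 genes at an unadjusted p under 0.05, and the remaining wrong splits gave 58 to 935. DESeq2 called 288 genes (257 higher, 31 lower), voom and voom with quality weights called 0, and edgeR without the filter on low counts called 24. Without wildtype 1, edgeR called 409 genes (294 higher, 115 lower), of which 408 had the same direction and 367 also an unadjusted p under 0.05 with all 6 libraries. Every library of that fit is also in the main one, so this agreement was largely fixed in advance and is no separate support. The controls left in that fit, wildtype 2 and 3, lacked 338 and 160 genes for which at least 10 counts were expected. Genes missing there appear higher in the knockout libraries, and how many of the 294 higher calls rest on this was not tested. Wildtype 1 was also the wildtype library most like the knockout libraries in log2 CPM. Scaling by library size alone moved the median of all genes to -0.21 and left 0 calls, with 475 genes higher and 2487 lower at an unadjusted p under 0.05.

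Of the 31 fixed gene lists, 18 passed the camera test at the preset correlation, 14 higher and 4 lower in the libraries labelled knockout. With a correlation estimated from the data 0 lists passed, each of the 18 having an adjusted p = 0.54 with an estimated correlation, and fry called 0 lists for a common direction and 0 for change in either direction. No member of any list passed the threshold over all genes, so member counts below are those adjusted over the list alone.

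**Figure D3:**
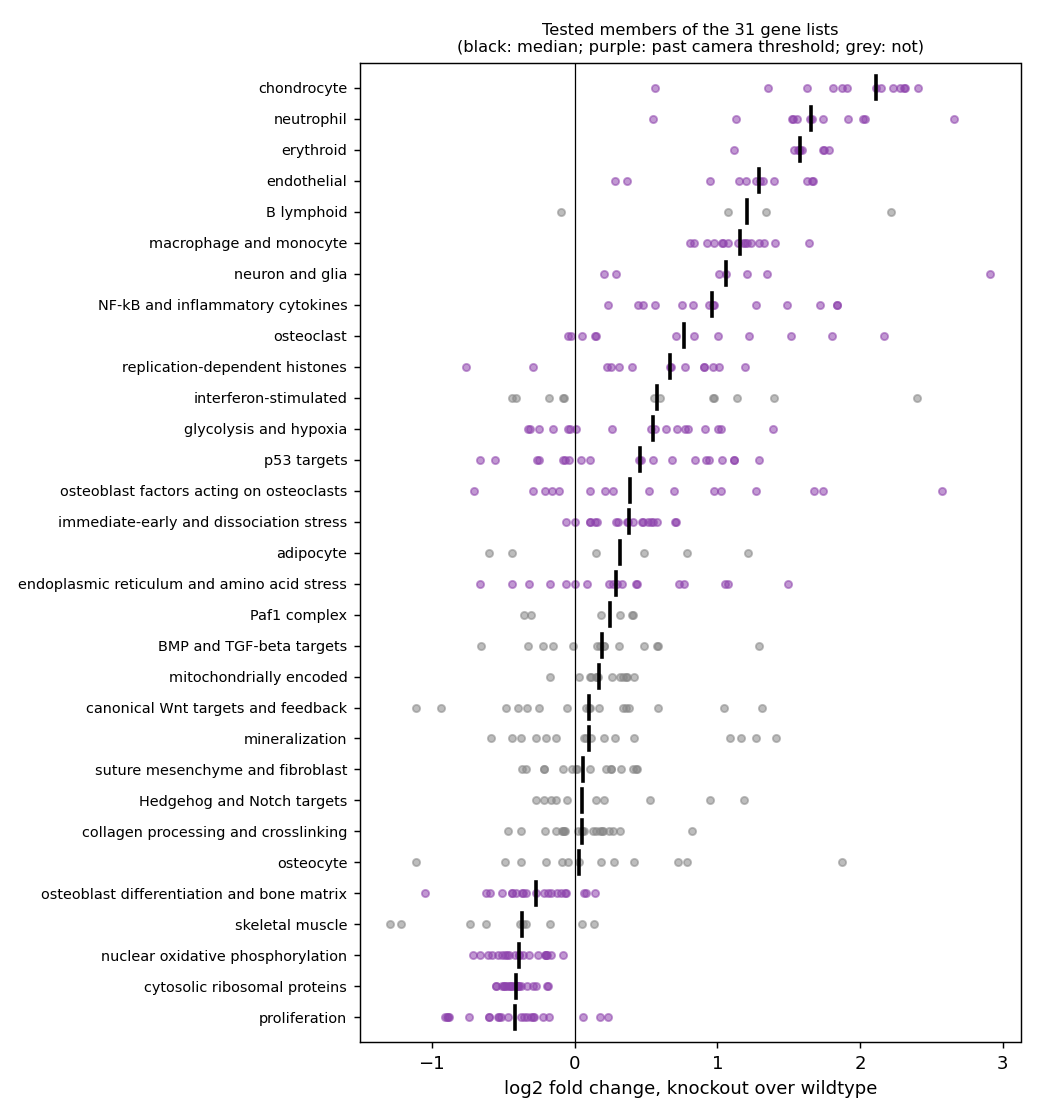
Log2 fold changes (knockout over wildtype, edgeR) of the tested members of the 31 lists, 1 point per gene, with the list median as a black bar. Lists in purple passed camera at the preset correlation, from chondrocyte (median 2.11) to proliferation (median -0.42), and grey lists did not.

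Cell division genes formed the list with the smallest p among those lower in the libraries labelled knockout. Of 22 proliferation genes 19 were lower, 10 of them past the threshold adjusted over the list alone, and 12 lay lower in every knockout library than in any wildtype library. The median log2 fold change was -0.42 (camera adjusted p = 1.01e-06, and adjusted p = 0.54 with an estimated correlation), while chondrocyte, endothelial and macrophage markers had medians of 2.11, 1.29 and 1.16. Cdk1, the kinase that drives entry into mitosis, measured 19.99 ± 2.74 CPM against 33.4 ± 5.25 (-0.74 ± 0.18), and its partner cyclin Ccnb1 5.06 ± 0.901 against 9.35 ± 1.597 (-0.88 ± 0.24). Mki67, a marker of cycling cells, did not follow, at 68.3 ± 4.44 against 65.5 ± 16.6 CPM (0.06 ± 0.20, and -0.14 with library size alone). The median of the list was also negative with wildtype 1 as the only control (-0.36). Replication-dependent histone genes lay higher, with 12 of 14 members positive and a median of 0.67 (camera adjusted p = 0.0154, and adjusted p = 0.54 with an estimated correlation). Their transcripts lack a poly(A) tail, and 28 of 31 named structural RNAs, most of which lack one too, were also positive (median 0.84). None of them passed adjusted over the list alone, as for H3c15 (0.97 ± 0.54) and the linker histone H1f4 (0.68 ± 0.38), and only 2 of the 14 reached a wildtype mean of 5 CPM. Under the stricter filter the histone list had an adjusted p = 0.0974.

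The lists of ribosomal proteins and of nuclear oxidative phosphorylation genes also passed as lower, in libraries with higher chondrocyte and macrophage markers (medians 2.11 and 1.16). All 22 ribosomal protein genes had a negative fold change, with a median of -0.41 (camera adjusted p = 2.54e-05, and adjusted p = 0.54 with an estimated correlation). All 21 nuclear genes of oxidative phosphorylation were negative too, with a median of -0.39 (camera adjusted p = 0.000148, and adjusted p = 0.54 with an estimated correlation). No member of either list passed adjusted over the list alone. Rps19 measured 67.7 ± 11.3 against 99.0 ± 25.6 CPM (-0.55 ± 0.22). Ndufb9, a subunit of complex I, measured 28.0 ± 4.34 against 45.8 ± 11.8 CPM (-0.71 ± 0.22), and Sdhb of complex II 41.4 ± 8.47 against 61.7 ± 16.1 CPM (-0.58 ± 0.23). Both differences rested on wildtype 2 and 3, since with wildtype 1 as the only control the medians were 0.02 and 0.07, and without wildtype 3 they were -0.23 and -0.20. Without wildtype 1 they were -0.62 and -0.59, and with library size alone -0.62 and -0.61. The genes of the mitochondrial genome had a median of 0.17 (camera adjusted p = 0.343), -0.06 with library size alone, with mt-Nd2 at 0.42 ± 0.26. At the preset correlation that list passed as higher without knockout 2 (adjusted p = 0.00772), without wildtype 3 (adjusted p = 0.0155) and with length and GC trends removed (adjusted p = 0.00158), against adjusted p = 0.815 with an estimated correlation over all 6 libraries. The mitochondrial median was 0.43 with wildtype 1 as the only control.

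Osteoblast differentiation and bone matrix genes were modestly lower in the libraries labelled knockout. Of 21 genes 18 were negative, with a median of -0.27 (camera adjusted p = 0.0026, and adjusted p = 0.54 with an estimated correlation), while chondrocyte, neutrophil, endothelial and macrophage markers had medians of 2.11, 1.66, 1.29 and 1.16 in the same comparison. Sp7, the osterix transcription factor required for osteoblast formation, measured 147 ± 30.4 CPM against 225 ± 18.2 (-0.62 ± 0.19), and the homeobox gene Dlx6 6.22 ± 2.51 against 12.8 ± 1.82 (-1.05 ± 0.29). Both were lower in every knockout library, yet no member passed adjusted over the list alone. The parathyroid hormone receptor Pth1r (-0.51 ± 0.22), the osteoblast membrane protein Ifitm5 (-0.59 ± 0.25) and the alkaline phosphatase gene Alpl (-0.44 ± 0.22) were negative with overlapping groups. Differences in Runx2 (-0.16 ± 0.24), Col1a1 (-0.10 ± 0.25), Bglap (-0.37 ± 0.42) and Ibsp (0.08 ± 0.18, and -0.14 with library size alone) were within 1 standard error. The list median was -0.14 without knockout 2 and -0.57 without knockout 3, and with wildtype 1 as the only control the list did not pass (median -0.16, adjusted p = 0.0534). With library size alone the median was -0.51, and with length and GC trends removed -0.44.

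Genes of mineralization and of osteocytes, the cells embedded in bone, went both ways. The mineralization list had a median of 0.10 (camera adjusted p = 0.458), with the phosphate transporter Slc20a1 at 46.0 ± 6.15 against 19.0 ± 6.87 CPM (1.27 ± 0.25) and the mineralization inhibitor Mgp at 203 ± 49.8 against 90.4 ± 35.5 CPM (1.17 ± 0.29). In the same libraries chondrocyte markers had a median of 2.11. Adjusted over the list alone, 2 of the 16 mineralization genes were higher and 0 lower. Phospho1, a phosphatase of matrix vesicles, measured 40.1 ± 8.92 against 60.2 ± 5.97 CPM (-0.59 ± 0.19). The osteocyte list had a median of 0.03 (camera adjusted p = 0.458), and 2 of 13 genes were higher and 1 lower adjusted over the list alone. Ackr3 (0.73 ± 0.19) and Fbln7 (0.79 ± 0.20) were higher in every knockout library, and Dkk1, a secreted Wnt inhibitor, was lower in every one (14.2 ± 1.76 against 30.5 ± 13.6 CPM, -1.11 ± 0.29). Dmp1, a matrix protein of osteocytes, measured 287 ± 28.5 against 214 ± 16.5 CPM (0.42 ± 0.16), Kera 7.08 ± 3.73 against 1.95 ± 1.63 CPM (1.87 ± 0.70) and Sost, the osteocyte gene for sclerostin, 8.28 ± 2.05 against 11.6 ± 4.41 CPM (-0.49 ± 0.31). With library size alone the medians of both lists were negative, at -0.13 and -0.18. Collagen processing genes had a median of 0.05 (camera adjusted p = 0.617), -0.15 with library size alone, with the lysyl hydroxylase Plod2 at 0.83 ± 0.22 and the collagen chaperone Fkbp10 at -0.37 ± 0.19, and 0 of 21 passed adjusted over the list alone.

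A list of factors through which osteoblasts act on osteoclasts, the cells that resorb bone, had a median of 0.39 (camera adjusted p = 0.0293, and adjusted p = 0.54 with an estimated correlation). Its members are also expressed by other cells, and in the same libraries the medians of chondrocyte, neutrophil, endothelial and macrophage markers were 2.11, 1.66, 1.29 and 1.16. Adjusted over the list alone, 2 of 16 were higher. They were Vegfa, an angiogenic growth factor (83.9 ± 16.9 against 41.3 ± 9.75 CPM, 1.02 ± 0.22), and Ptgs2, the inducible cyclooxygenase (173 ± 24.0 against 51.7 ± 30.1 CPM, 1.74 ± 0.43). The cytokines Il6 (1.27 ± 0.46) and Il11 (2.58 ± 0.82, at 1.47 ± 0.54 against 0.225 ± 0.219 CPM) were positive and did not pass. The pair most directly tied to osteoclast formation differed by less than 1 standard error, with the RANKL gene Tnfsf11 at 13.2 ± 1.95 against 12.3 ± 2.75 CPM (0.11 ± 0.22, and -0.080 with library size alone) and the osteoprotegerin gene Tnfrsf11b at 13.8 ± 1.28 against 15.4 ± 3.42 CPM (-0.16 ± 0.20). The list did not pass without knockout 1 (adjusted p = 0.0666), without wildtype 3 (adjusted p = 0.0614), with either other filter (adjusted p = 0.0534 and 0.0605) or with wildtype 1 as the only control (adjusted p = 0.0756), and its median was 0.26 with the stricter filter and 0.2 with library size alone.

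Markers of cells other than osteoblasts were higher in the libraries labelled knockout for most of the cell types examined. All 13 chondrocyte markers were higher and passed adjusted over the list alone, with a median of 2.11 (camera adjusted p = 1.08e-07, and adjusted p = 0.54 with an estimated correlation). Col2a1, the collagen of cartilage, was the most abundant at 9548 ± 5488 against 1804 ± 2152 CPM (2.40 ± 0.79), followed among the named genes by Acan, the cartilage proteoglycan (710 ± 289 against 202 ± 149 CPM, 1.81 ± 0.49). Sox9, the chondrocyte transcription factor (1.35 ± 0.36), Hapln1 (1.63 ± 0.44) and Snorc (2.12 ± 0.58) were also higher in every knockout library. Mean log2 CPM over the list was 9.24, 8.33 and 8.10 in knockout 1, 2 and 3, 7.74 in wildtype 1, and 5.46 and 5.42 in wildtype 2 and 3. With wildtype 1 as the only control the median was 0.97.

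Endothelial markers had a median of 1.29 (camera adjusted p = 6.35e-06, and adjusted p = 0.54 with an estimated correlation), with all 12 positive and 8 past adjusted over the list alone. Examples were Emcn (1.63 ± 0.41), Vwf (1.67 ± 0.52), Plvap (1.15 ± 0.35) and the receptor Tie1 (1.20 ± 0.36). The median was 2.02 without wildtype 1 and 0.47 with wildtype 1 as the only control. Blood cell markers were higher too. Of 16 macrophage and monocyte markers 15 passed adjusted over the list alone, with a median of 1.16 (camera adjusted p = 2.04e-07, and adjusted p = 0.54 with an estimated correlation). Cd14 measured 21.5 ± 7.27 against 6.93 ± 2.43 CPM (1.64 ± 0.31), Cd74 20.5 ± 6.08 against 7.77 ± 3.70 (1.40 ± 0.37), Csf1r 54.3 ± 18.4 against 23.1 ± 9.04 (1.23 ± 0.33) and Lyz2 42.9 ± 16.7 against 21.1 ± 3.84 (1.03 ± 0.28). The macrophage median was 0.76 without knockout 1.

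Neutrophil markers had a median of 1.66 (camera adjusted p = 1.57e-05, and adjusted p = 0.54 with an estimated correlation), with 7 of 12 past adjusted over the list alone, among them Ngp (2.03 ± 0.50), Lcn2 (2.02 ± 0.58) and Ltf (1.53 ± 0.48), and a median of 0.88 without knockout 1. Osteoclast markers had a median of 0.77 (camera adjusted p = 0.000639, and adjusted p = 0.54 with an estimated correlation), and 4 of 12 passed adjusted over the list alone. These were Mmp9 (184 ± 17.3 against 91.9 ± 25.2 CPM, 1.00 ± 0.21), Acp5, the tartrate-resistant acid phosphatase (37.98 ± 3.65 against 23.2 ± 1.45 CPM, 0.71 ± 0.15), Atp6v0d2 (1.81 ± 0.55) and Nfatc1 (0.83 ± 0.27), and the osteoclast median was 0.39 without knockout 1, 0.42 with the stricter filter and 0.47 with wildtype 1 as the only control. Erythroid genes had a median of 1.58 (camera adjusted p = 0.00991, and adjusted p = 0.54 with an estimated correlation) and none of 9 past adjusted over the list alone. The alpha-globin gene Hba-a2 measured 98.2 ± 70.7 against 28.5 ± 17.7 CPM (1.78 ± 0.73), and the erythroid list did not pass without knockout 1 (adjusted p = 0.0592), without wildtype 2 (adjusted p = 0.116) or with wildtype 1 as the only control (adjusted p = 0.166). Neuron and glia markers had a median of 1.06 (camera adjusted p = 0.00575, and adjusted p = 0.54 with an estimated correlation), 1.88 without wildtype 1, with S100b at 1.01 ± 0.39.

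The lists of 4 cell types did not pass the camera test. B lymphoid markers had a median of 1.21 over 4 genes (camera adjusted p = 0.0508, and adjusted p = 0.54 with an estimated correlation), with Blnk at 1.34 ± 0.48. At the preset correlation this list passed with library size alone (adjusted p = 0.019), without the filter on low counts (adjusted p = 0.0018), with length and GC trends removed (adjusted p = 0.0352) and without knockout 2, knockout 3, wildtype 2 or wildtype 3. Skeletal muscle markers had a median of -0.37 (camera adjusted p = 0.458, and adjusted p = 0.815 with an estimated correlation), and at the preset correlation passed as lower without knockout 1 (adjusted p = 0.0163) and without wildtype 3 (adjusted p = 0.000138). The muscle median was -0.82 with wildtype 1 as the only control. Acta1 was at -0.73 ± 0.72 and Tnnc2 at -1.22 ± 0.89. Adipocyte markers had a median of 0.32 (camera adjusted p = 0.458), with Cebpa at 0.49 ± 0.17 and Cd36 at 0.79 ± 0.35. Suture mesenchyme and fibroblast markers had a median of 0.06 (camera adjusted p = 0.801), -0.15 with library size alone, with Twist1 at 0.44 ± 0.18. None of the members of these 4 lists passed adjusted over the list alone.

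**Figure D4:**
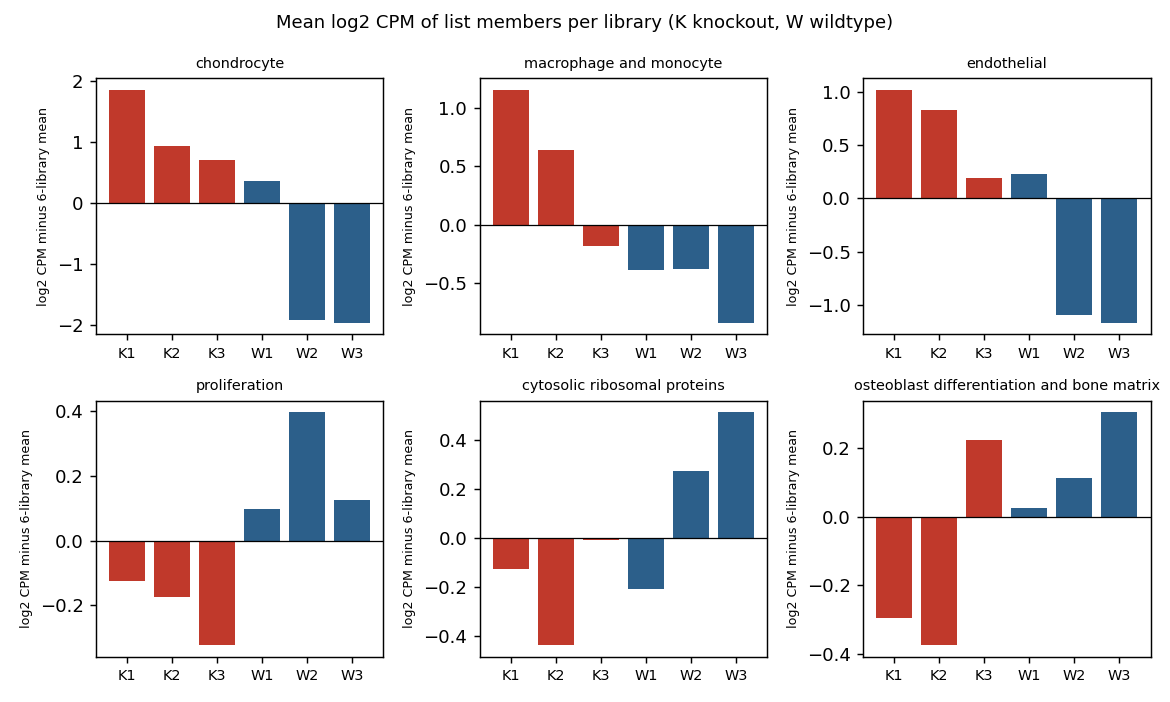
Mean log2 CPM of the members of 6 lists in each library, minus the mean over all 6 libraries (red K1 to K3 knockout, blue W1 to W3 wildtype). For chondrocyte markers wildtype 1 (7.74 before centring) lies nearer to knockout 3 (8.10) than to wildtype 2 (5.46) and wildtype 3 (5.42).

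Inflammatory genes were higher alongside the macrophage and neutrophil markers, whose medians were 1.16 and 1.66. All 14 NF-kB and cytokine genes were positive, 9 past adjusted over the list alone, with a median of 0.96 (camera adjusted p = 6.35e-06, and adjusted p = 0.54 with an estimated correlation). The cytokine Il1b measured 15.5 ± 6.54 against 4.37 ± 1.62 CPM (1.84 ± 0.38), the chemokine Ccl7 17.4 ± 4.88 against 6.16 ± 3.02 (1.49 ± 0.38) and Tnfaip3, a feedback inhibitor of NF-kB, 88.7 ± 21.3 against 49.8 ± 13.96 (0.83 ± 0.25). The median was 0.60 without wildtype 3 and 0.57 with wildtype 1 as the only control. Interferon-stimulated genes had a median of 0.58 (camera adjusted p = 0.458), with Cxcl10 at 1.39 ± 0.57 and 0 of 12 past adjusted over the list alone. Immediate-early genes, which respond within minutes to stimuli such as cell dissociation, were positive in 18 of 19 cases with a median of 0.38 (camera adjusted p = 0.00671, and adjusted p = 0.54 with an estimated correlation). None passed adjusted over the list alone, as for Egr3 (0.71 ± 0.26), Ier3 (0.70 ± 0.28) and Junb (0.54 ± 0.23). The immediate-early list had a median of 0.62 without wildtype 1, and it did not pass without wildtype 3 (median 0.14, adjusted p = 0.0642) or with wildtype 1 as the only control (median 0.08, adjusted p = 0.297), and its median was 0.2 with library size alone.

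The lists of glycolysis and hypoxia, endoplasmic reticulum and amino acid stress, and p53 targets also passed as higher, alongside the markers of other cells, with medians of 2.11 for chondrocyte and 1.16 for macrophage markers. Glycolysis and hypoxia genes had a median of 0.55 (camera adjusted p = 0.0167, and adjusted p = 0.54 with an estimated correlation), with 4 of 18 past adjusted over the list alone, Vegfa, Ero1a (19.7 ± 0.664 against 11.5 ± 2.09 CPM, 0.78 ± 0.18), Adm (0.92 ± 0.26) and the glucose transporter Slc2a1 (33.2 ± 14.4 against 12.7 ± 6.59 CPM, 1.39 ± 0.43). Endoplasmic reticulum and amino acid stress genes had a median of 0.29 (camera adjusted p = 0.0367, and adjusted p = 0.54 with an estimated correlation), with 3 of 18 higher adjusted over the list alone. These were the transcription factor gene Ddit3, also called CHOP (62.9 ± 19.7 against 22.2 ± 11.4 CPM, 1.5 ± 0.35), Chac1 (1.08 ± 0.24) and the chaperone Hspa5 (1184 ± 106 against 714 ± 164 CPM, 0.73 ± 0.21), while Phgdh of serine synthesis was at -0.66 ± 0.23. Targets of p53 had a median of 0.46 (camera adjusted p = 0.0311, and adjusted p = 0.54 with an estimated correlation), with 2 of 20 higher adjusted over the list alone, Plk2 (74.1 ± 9.60 against 34.2 ± 8.22 CPM, 1.12 ± 0.21) and Btg2 (0.85 ± 0.23). Cdkn1a, the cell cycle inhibitor p21, measured 228 ± 24.4 against 166 ± 9.17 CPM (0.45 ± 0.16), Mdm2 was at 0.69 ± 0.22 and Phlda3 at -0.66 ± 0.20. Without knockout 1 the glycolysis, stress and p53 lists did not pass (adjusted p = 0.0589, 0.062 and 0.0519), nor did they without the filter on low counts (adjusted p = 0.0622, 0.136 and 0.117). The stress list also did not pass without wildtype 1 (adjusted p = 0.307), without wildtype 3 (adjusted p = 0.0965) or with library size alone (adjusted p = 0.0722), the glycolysis list without wildtype 1 (adjusted p = 0.0886), and the p53 list without wildtype 3 (adjusted p = 0.0883) or with wildtype 1 as the only control (adjusted p = 0.293). The glycolysis median was 0.26 without wildtype 3, 0.27 with wildtype 1 as the only control and 0.36 with library size alone. The p53 median was 0.28 without knockout 1, 0.26 with library size alone and 0.09 with wildtype 1 as the only control, and the stress median 0.08 with library size alone.

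Genes of the Paf1 complex and of signalling pathways showed no common direction. The Paf1 complex had a median of 0.25 over 6 subunits (camera adjusted p = 0.458), with Rtf1 (28.3 ± 1.49 against 21.3 ± 3.02 CPM, 0.41 ± 0.16) and Paf1 (32.7 ± 2.57 against 24.6 ± 3.23 CPM, 0.41 ± 0.16) positive and Wdr61 at -0.30 ± 0.18. Canonical Wnt targets had a median of 0.10 (camera adjusted p = 0.995), -0.11 with library size alone. Adjusted over the list alone, 1 of 17 was higher, the secreted inhibitor Sfrp4 (70.3 ± 30.8 against 33.9 ± 5.76 CPM, 1.05 ± 0.28), and 1 was lower, Dkk1. Axin2, a widely used Wnt reporter gene, measured 14.8 ± 1.03 against 11.3 ± 3.57 CPM (0.38 ± 0.24), Tnfrsf19 was at -0.48 ± 0.20 and Tcf7 at -0.40 ± 0.18. Hedgehog and Notch targets had a median of 0.05 (camera adjusted p = 0.487), -0.14 with library size alone, with the Notch target Hes1 at 80.3 ± 2.76 against 55.8 ± 6.49 CPM (0.53 ± 0.15) and Nrarp at 0.95 ± 0.40, and 0 of 10 passed adjusted over the list alone. BMP and TGF-beta targets had a median of 0.19 (camera adjusted p = 0.329), and 0 with library size alone. Ccn1 was at -0.65 ± 0.24 and Smad7 at 0.49 ± 0.21.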

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

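Robust estimates, the removal of unnamed IDs and Lars2, the removal of length and GC trends, the voom and estimated-correlation fits without wildtype 1, and wildtype 1 as the only control were tests chosen only after the results had been seen.

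The count of 0 genes from edgeR (1974 at an unadjusted p under 0.05) stayed at 0 with the 3 other scalings, the stricter filter, voom with or without quality weights, robust estimates, the unnamed IDs and Lars2 left out, and wildtype 1 as the only control. It was 24 without the filter on low counts and 288 with DESeq2. Leaving out each library in turn gave 0 to 409, the 409 without wildtype 1, where voom called 259, of which 251 were among the 409. DESeq2 shared 150 of its 288 with the 409. The cause of these differences between tools was not tested. Cdc73 kept its direction and missed the threshold under all 15 alternatives run for it, from -0.57 to -0.23. The correlations of deviations for shared replicate numbers were 0.12, -0.07 and 0.22, and knockout 2 correlated best with wildtype 1 (0.35). These values do not show that the numbers pair the libraries, and with 3 libraries per group they cannot exclude it. The replicate block gave 236 genes (226 higher, 10 lower), and 19 lists, with a median of 0.117 for the Wnt list, whose camera direction turned.

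The 18 lists past the threshold became 0 with an estimated correlation, 0 with fry for direction, 0 with fry for mixed change and 0 with an estimated correlation without wildtype 1. The correlation estimated within lists had a median of 0.321 against the preset 0.01. Other settings gave 13 to 20 lists, 14 to 20 when 1 library was left out and 13 with wildtype 1 as the only control. With length and GC trends removed 20 passed, and the ribosomal protein and oxidative phosphorylation lists stayed lower (medians -0.37 and -0.30 on log2 CPM, adjusted p = 0.00158 and 0.0041 by camera). Across genes, log2 fold change correlated with transcript length at a Spearman's rho of 0.31 and with GC content at -0.04 (12780 genes, 94.6% of those tested).

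Of the values of 111 named genes other than Cdc73 over these settings, 1515 kept direction and side of the threshold, 133 passed it in the same direction (49 with DESeq2, 40 with the replicate block, 34 without wildtype 1, 10 without the filter) and 16 turned, none of the last past it. With library size alone Ibsp was -0.135, Tnfsf11 -0.080 and Mki67 -0.143, and Ddx3y was -0.008 with voom and -0.277 with quality weights. Leaving out 1 library gave ranges of -0.261 to 0.658 for Xist, -0.367 to 0.957 for Ddx3y, -0.40 to 0.018 for Runx2, -0.331 to 0.006 for Col1a1, -0.041 to 0.145 for Ibsp, -0.839 to 0.207 for Bglap, -0.029 to 0.288 for Tnfsf11, -0.301 to 0.014 for Tnfrsf11b and -0.116 to 0.246 for Mki67.

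Of the values of single lists, 450 kept direction and side, 15 passed in the same direction, 96 no longer passed and 28 turned in camera's direction, which can differ in sign from the median given here. Of the turned lists, only ribosomal proteins (0.017) and oxidative phosphorylation (0.067) had passed in the main test, and both turned with wildtype 1 as the only control. The Paf1 complex (0.066), adipocyte (0.024) and Hedgehog and Notch (-0.047) lists turned with that control too. With library size alone collagen processing was -0.147 and skeletal muscle -0.522. Without the filter collagen processing was 0.042, mesenchyme 0.048 and Wnt 0.092, and with DESeq2's size factors Wnt was 0.109. With length and GC trends removed muscle was -0.204 and Wnt -0.099. With an estimated correlation without wildtype 1, collagen processing was 0.041 and Wnt 0.032. Leaving out 1 library gave medians of -0.095 to 0.335 for mineralization, -0.027 to 0.099 for collagen processing, 0.023 to 0.082 for mesenchyme, -1.21 to -0.014 for muscle, -0.020 to 0.329 for adipocyte, -0.061 to 0.156 for Wnt, 0.158 to 0.841 for interferon-stimulated and -0.082 to 0.391 for mitochondrially encoded genes. The causes were not tested. At these depths and this spread, the simulated test recovered 48% of 2-fold changes in knockout against wildtype among genes with a mean of at least 5 CPM.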

Other observations

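The tests of a lower osteoblast share, the scaling behind the structural RNAs, a sample swap, a wrong label, lost molecules and other splits of the libraries were chosen only after the results they measure had been seen.

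Structural RNAs lay above genes of similar level in their log2 fold change of knockout over wildtype. Of 31 named small nucleolar, small nuclear, guide, ribonuclease and mitochondrial ribosomal RNAs, 28 had a positive log2 fold change, with a median of 0.84, above 99.94% of 10000 random lists matched on level (their median was 0.18). The 22 small nucleolar RNAs among them had a lower median of 0.47, with 19 positive. The other classes, with few members each, had medians of 0.91 to 1.6. With wildtype 1 as the only control the median of all 31 was 0.62. Rmrp, the RNA of ribonuclease MRP, measured 88.7 ± 24.8 against 37.2 ± 15.4 CPM (1.26 ± 0.31), and the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were at 0.94 ± 0.23 and 0.87 ± 0.22. The long nuclear RNAs Malat1 (314 ± 67.8 against 121 ± 43.1 CPM, 1.37 ± 0.27) and Neat1 (23.1 ± 2.02 against 9.57 ± 4.74 CPM, 1.26 ± 0.30) were higher in every knockout library, wildtype 1 included in the comparison. Gene ID 100861531 was at 1.11 ± 0.24, and Lars2, a mitochondrial leucyl-tRNA synthetase gene, at 1.20 ± 0.24. Counts of Lars2 stayed at 8.2% to 9.96% of those of that ID in the 6 libraries, so a change of Lars2 itself cannot be told apart from one of that ID. None of the genes named here passed edgeR's quasi-likelihood test over all genes, each having an adjusted p of 0.27.

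The scaling moves all genes of a library alike, so it is argued against as the source of the distance of 0.65 between the median of these structural RNAs and that of the random lists. The median of 0.84 lay above the 95th percentile of the random lists (0.48), as more RNA without a poly(A) tail in the knockout libraries would give. That is consistent with a difference in RNA selection between libraries as a candidate explanation. A change in these RNAs caused by the genotype stays open and untested, because both would follow the labels.

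Xist, transcribed from the inactive X chromosome, and the Y-linked gene Ddx3y were both present in every library, at 113 to 368 CPM and 3.75 to 43.8 CPM. Their log2 fold changes were 0.37 ± 0.36 and 0.45 ± 0.70, neither past the threshold in edgeR's quasi-likelihood test.

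Markers of several other cell types were higher in the libraries labelled knockout. Among members with a wildtype mean of at least 5 CPM, the 25th percentile of the chondrocyte log2 fold changes (1.81, 13 genes) lay above the 75th percentile of the endothelial (1.30, 9 genes) and macrophage ones (1.23, 10 genes), and by at least 0.12 when any 1 library was left out. A lower share of osteoblast RNA alone would raise every other cell type alike only if osteoblasts expressed none of the markers. Markers rose unequally within lists, the lowest being endothelial Egfl7 (0.28 ± 0.25) and Esam (0.37 ± 0.27) and chondrocyte Col11a2 (0.56 ± 0.21). The distance therefore cannot decide on a lower share of osteoblast RNA. With wildtype 1 as the only control the distance was 0.30 from the endothelial and -0.45 from the macrophage markers. The choice between TMM and library size is argued against as the source by its small effect. With library size alone the chondrocyte median was 1.96 and that of all genes -0.21. With TMM factors of 0.813 to 1.09 these medians could hardly have moved more. Camera compares a list with the other genes, so its p says little about the scaling (adjusted p = 5.6e-11 by camera at the preset correlation, against adjusted p = 0.54 with an estimated correlation after TMM scaling). The 13 chondrocyte markers moved as a block, with 91.8% of their variance along 1 component against 82.7% at the 95th percentile of 1000 random lists, and Col2a1 ran from 518 CPM in wildtype 2 to 15630 CPM in knockout 1, which is consistent with RNA of cartilage cells in the sorted material, a source that the GFP sort should remove. Expression of these genes in the sorted osteoblasts themselves, with or without an effect of the genotype, would also move them together and stays open and untested.

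By correlation of log2 CPM, wildtype 1 lay nearer to the libraries labelled knockout than to wildtype 2 and 3. By chi-square per degree of freedom on counts, it was nearest to wildtype 2, at 32.3. The value was 58.1 with wildtype 3, and 56.8, 78.3 and 75.3 with knockout 1, 2 and 3. By correlation, a swap with a knockout library cannot be told apart from correct labels. The highest correlation of any knockout library with wildtype 2 or 3, 0.939 for knockout 3, lay below the lowest among the knockout libraries (0.974). It lay above that of wildtype 2 with wildtype 3 (0.925). The chi-square values followed the labels, at 19.7 to 41.7 among the knockout libraries and 42.3 between wildtype 2 and 3. Between the knockout libraries and wildtype 2 or 3 they ran from 94.0 to 150.3. The measures differ, so a swap is not settled. Wildtype 2 and 3 lacked 338 and 160 genes for which at least 10 counts were expected from the other libraries, against 5 or fewer in each of the other 4 libraries, yet lost molecules do not account for the whole pattern, since among 348 genes at a mean of at least 200 CPM the lowest correlation of wildtype 1 with a knockout library still exceeded its highest with wildtype 2 or 3 by 0.029. By Cdc73, a wrong label on wildtype 1 alone cannot be told apart from a true wildtype library. Cdc73 at 20.5 CPM in wildtype 1 was above every knockout library, while wildtype 2 lay below them. The most abundant ID without a name took 11.23% of the counts in wildtype 1, and 9.67% and 10.44% in wildtype 2 and 3. It took 16.66%, 20.58% and 20.68% in knockout 1, 2 and 3. This share and the lowest chi-square value, with wildtype 2, went with the label. They are not separate, since abundant features such as that ID weigh most in the chi-square. The higher correlations of wildtype 1 with the knockout libraries did not go with the label. Yet wildtype 2 and 3 each correlated best with wildtype 1, at 0.94 and 0.945, against 0.906 to 0.939 with the knockout libraries. A wrong label is therefore not settled either.

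The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest of the other splits also gave 0, so all 10 gave as many. With 0 calls in the real split that outcome was fixed in advance and decides nothing. For the gene lists the real split gave 18 and the highest other split also gave 18, so 2 of the 10 splits gave as many. That other split, which groups wildtype 1 with knockout 1 and 2, had 1991 genes at an unadjusted p under 0.05 against 1974 for the real one. The remaining splits had 58 to 935 such genes and 6 to 13 lists past the threshold.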
